A study of Mus musculus with 7 samples.

How the data were processed

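Gene expression was measured in 7 RNA samples of D3 mouse embryonic stem cells, 2 from wild type cells and 5 from calreticulin knockout cells. Per the labels, total RNA was extracted with Trizol, biotin-labelled cRNA was prepared and hybridised to Affymetrix Mouse 430 2.0 arrays, and each sample was a pool of replicate cultures that counted as a separate biological replicate. The labels do not say whether the knockout samples came from 1 clone or from several, so p-values measure the spread between these samples. Each sample was placed in its group, and numbered within it, by its title.

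The deposited values are intensities, 1 signal per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; the version is not given in the sources used here. The mean of the deposited intensities without the lowest and highest 2% of probe sets was 500.0 on every array. Every array was therefore already scaled to a common level, and each signal is relative to the rest of its own array. The table held no detection calls, so a low signal could not be separated from background by the authors' own test. Array medians ran from 92.6 to 124.9, a ratio of 1.35, which is under the limit of 1.5 set for a further normalization, and none was applied.

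Signals were converted to log2(signal + 20.2), where 20.2 is the 20th percentile of all values in the table. Differences are knockout minus wild type on this scale, which understates the change of dim probe sets. Of 45101 probe sets, 64 Affymetrix control probe sets were set aside, and 27022 had a mean log2 value above the 40th percentile and were tested. The platform annotation gave 34958 probe sets 1 gene symbol, 932 several and 9211 none; 34754 were matched to RefSeq genes of the assembly GRCm38.p6 by their gene identifier, and that table served for current symbols, chromosomes and the order of neighbouring genes. The array files name no genome build, so no coordinates are given, and probe sets with several symbols are not given a gene name. A gene was represented by its brightest probe set with a single symbol, which gave 13120 genes.

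Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in mean signal, two-sided, Benjamini-Hochberg adjusted p under 0.05), without further covariates. Of 34 gene lists fixed from textbook knowledge, 33 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The Y chromosome list had 3 measured genes and is given as values. The genes of 20 chromosomes, 13055 in all, were tested in the same way. Control probe sets were compared with exact permutation tests over the 21 ways to choose 2 of 7 arrays, which cannot give a p below 0.048.

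Genes were named by a fixed rule. Calr was always named. Among genes past the threshold whose 5 knockout signals all lay on the same side of both wild type signals, the 12 largest rises and the 12 largest falls were named, leaving out clone and locus identifiers. From each list up to 2 called members per direction were named, and where none was called, up to 2 members with the highest mean signal were given as values. Neighbours of Calr and Y chromosome genes could be given individually. The comparisons, lists, thresholds, naming rule and first alternatives were fixed before the data were examined; other genes are said to have been chosen after their values were seen.

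The fits were tested on simulated data with 200 changed items, made from the means and residual spreads of the real arrays. Noise was drawn independently for each item and array. Correlations between libraries or genes were therefore not simulated, and the shares below hold only without them. In the comparison of 2 with 5 arrays over 13120 genes, a log2 change of 1 was called in 10% of the changed genes, a change of 2 in 72%, a change of 3 in 96% and a change of 4 in 100%, with 7 false calls. Over 27020 probe sets the shares were 6%, 54%, 80% and 96%, with 3 false calls. With 2 wild type and 3 knockout arrays they were 0%, 32%, 78% and 82%, with 1 false call. A call can thus be lost in such a fit through fewer arrays alone. The number of arrays limits the precision of every value.

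Alternatives were quantile normalization, centring on array medians, other filters, other pseudocounts, a variance model without a trend, array weights, other rules for the probe set that stands for a gene, other set tests, the replicate number as a block, and leaving out each array. After the data were seen, fits without knockout libraries 2 and 3, and with these 2 libraries as a batch term, were added, the former also with an estimated correlation, because their poly-A control signals stood apart. Figures were drawn with matplotlib 3.10.9.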

Results

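The series asks which transcripts change when calreticulin, a calcium-binding chaperone of the endoplasmic reticulum (ER) lumen encoded by Calr, is removed from mouse embryonic stem cells. D3 is an established mouse embryonic stem cell line. The comparison rests on 2 wild type and 5 knockout libraries, each hybridised to its own array.

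Calr, on chromosome 8, was the first gene examined, since it checks the labels. Its brightest probe set had a signal of 11650 ± 1146 (SD, n = 2) in wild type libraries and 912 ± 205 (SD, n = 5) in knockout libraries, which was 7.83% of the wild type mean. The difference was -3.68 on the log2 scale (SE 0.30, limma adjusted p = 0.00595 over probe sets). The other 2 Calr probe sets differed by -3.50 (limma adjusted p = 0.0102) and -3.28 (adjusted p = 0.0189), and the latter lost its call without knockout library 1 or 5 (adjusted p = 0.0749 and 0.0715). All 5 knockout libraries lay below both wild type libraries with each probe set, and their signals of 486 to 1080 stayed above the array medians. Whether these probe sets lie inside the deleted part of the gene could not be settled from the tables used here. Without wild type library 1 or wild type library 2 the targeted gene difference was -3.58 or -3.78 over genes and no longer passed the threshold (adjusted p = 0.176 and 0.137).

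Beyond Calr, 5 probe sets passed the threshold, 3 of them with a named gene. Snhg14, a long non-coding RNA gene of the imprinted region on chromosome 7, rose from 13.2 ± 9.12 to 2783 ± 1266 with its called probe set, a difference of 6.30 (SE 0.43, limma adjusted p = 0.00223). Its other 2 probe sets were higher in all 5 knockout libraries too, by 2.69 and 1.79, without passing the threshold (adjusted p = 0.575 for each). The latter, the brightest of the gene, already stood at 1004 ± 437 in wild type libraries and at 3715 ± 1841 in knockout libraries. Mid1, an X-linked gene for a microtubule-associated ubiquitin ligase, fell from 864 ± 449 to 82.8 ± 10.8, a difference of -3.01 (SE 0.31, adjusted p = 0.0184). The call rests on 1 probe set, since the other 2 of Mid1 were under the signal filter. Of these, 1 was lower in all 5 knockout libraries (96.0 ± 15.3 and 37.4 ± 30.7). The other overlapped between the groups (3.80 ± 1.56 and 17.5 ± 14.0). Bcl11b, a zinc finger transcription factor gene on chromosome 12, rose from 107 ± 40.4 to 646 ± 119, a difference of 2.41 (SE 0.30, adjusted p = 0.0491), and its other 3 tested probe sets were higher in all 5 knockout libraries by 1.20 to 1.85. Snhg14 and Bcl11b were chosen after their values were seen. Without knockout libraries 2 and 3 together, Snhg14 still passed (5.84, adjusted p = 0.000332), and Mid1 (-3.01, adjusted p = 0.0682) and Bcl11b (2.26, adjusted p = 0.133) did not. With a lone wild type library Snhg14 was not called either, at 6.02 without library 1 and 6.59 without library 2. Bcl11b lost its call whichever single library was left out (adjusted p from 0.101 to 0.290), and Mid1 without wild type library 1 (0.0990) or 2 (0.129) or knockout library 1 (0.0741), 4 (0.0574) or 5 (0.0588).

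The remaining called probe sets carry no gene name here. A probe set without a symbol in the annotation fell from 569 ± 84.4 to 71.2 ± 22.3 (log2 difference -2.72, limma adjusted p = 0.0189; 0.0749 without knockout library 1, 0.0574 without knockout library 4, 0.0566 without knockout libraries 2 and 3). A probe set annotated to 2 genes rose from 0.80 ± 0.28 to 321 ± 129 (3.95, adjusted p = 0.00743), while 4 further tested probe sets of the same annotation differed by -0.21 to 0.89 and did not pass. An unadjusted limma p under 0.05 was found at 2274 of 27022 probe sets, where 1351 would be expected with no difference. That number was 1405 or 1369 without knockout library 2 or 3, and 2755, 3270 and 2065 without knockout library 1, 4 or 5. The excess thus depends on the libraries used, and it also moved with the choice of wild type library. In all, 8 probe sets passed the adjusted threshold, 3 higher and 5 lower. Without wild type library 1 or 2 the count was 0, without knockout library 1, 4 or 5 it was 4, 5 and 5, and without knockout libraries 2 and 3 together it was 5.

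**Figure D1:**
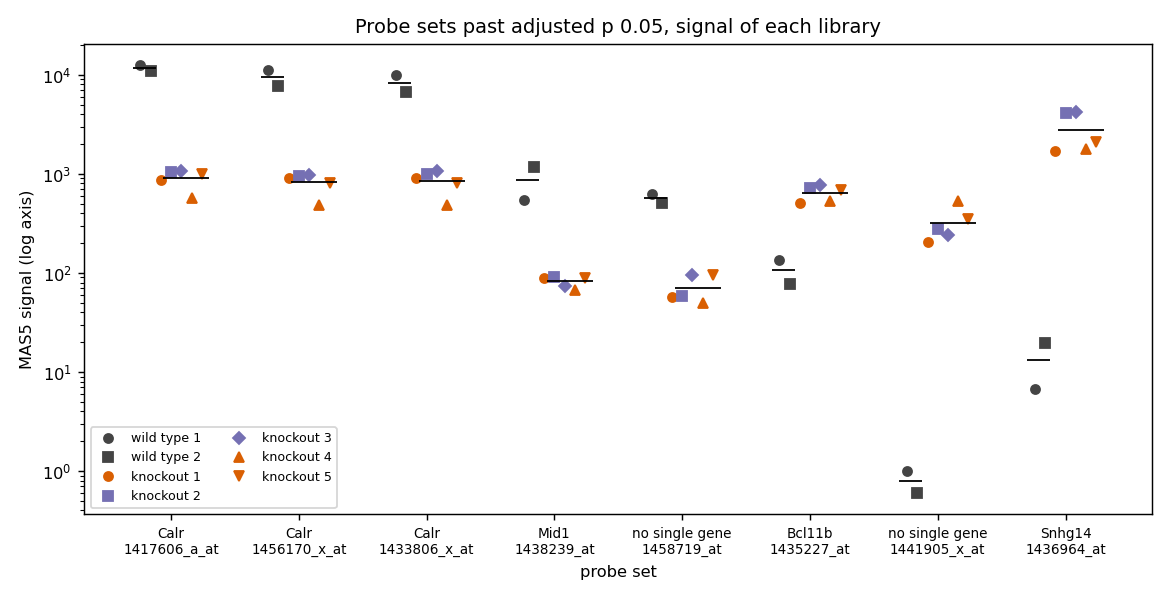
MAS5 signal (log axis) of each library for the 8 probe sets past adjusted p 0.05, with horizontal lines at the group means of 2 wild type and 5 knockout libraries. The 3 Calr probe sets lie between 486 and 1080 in the knockout libraries and at 6682 or more in the wild type libraries, and Snhg14 lies at 19.6 or less in wild type and at 1706 or more in knockout libraries.

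With 1 probe set per gene, 2 of 13120 genes passed the threshold, Calr (-3.68, limma adjusted p = 0.00531) and Mid1 (-3.01, adjusted p = 0.0209), both lower in the knockout cells. Bcl11b missed it (2.41, adjusted p = 0.0515). Vim, which encodes the intermediate filament vimentin, had a signal of 10107 ± 2175 in wild type and 3023 ± 882 in knockout libraries (log2 difference -1.77, SE 0.32, adjusted p = 0.589), and all of its 3 probe sets were lower in the 5 knockout libraries. At an unadjusted p under 0.05 there were 1057 genes, 611 higher and 446 lower, against 656 expected. At an unadjusted p under 0.001 there were 16, against 13.1 expected. The 2 groups did not overlap at 13.8% of genes, 841 higher and 976 lower, against 9.52% if the 7 libraries were exchangeable. Knockout libraries 2 and 3 resembled each other and genes are not independent, so the 2 shares are not a test of the groups. With knockout libraries 2 and 3 as a batch term, an alternative added after the data were seen in which the other 3 knockout libraries carry the difference, 7 genes passed. Bcl11b was higher (2.26), and Calr (-3.84), Mid1 (-3.01), Dlk1 (-2.21), Vim (-2.05), Ntn1 (-1.84) and Erdr1 (-1.17) were lower, with adjusted p from 0.00106 to 0.0434. These differences equal those of the fit without knockout libraries 2 and 3, where 1 gene passed. The batch fit differs in its estimate of spread, which also draws on this close pair (r = 0.985). In knockout libraries 2 and 3 the Dlk1 signals were 680 and 780, against 530 ± 219 in wild type libraries, and the Ntn1 signals were 2358 and 2528 against 524 ± 129. The Erdr1 signals were 14600 and 16090 against 12738 ± 116, so these 3 genes were not lower in all knockout libraries. Bcl11b, Vim, Dlk1, Ntn1 and Erdr1 were chosen after their values were seen. The count was 1 without knockout library 1, 4 or 5, 1 without wild type library 1, 0 without wild type library 2, and 1 without knockout libraries 2 and 3. Calr was the remaining gene in each case with a knockout library left out, and Mid1 without wild type library 1. Mid1 lost its call without wild type library 2 (adjusted p = 0.137), knockout library 1 (0.0761), 4 (0.109) or 5 (0.0738).

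Knockout libraries 2 and 3 stood apart from the other 5 libraries. Across the tested probe sets they correlated with each other at r = 0.985 (Pearson, across probe sets, which are not independent replicates) and with the other libraries at 0.843 to 0.902, while the other 5 correlated with one another at 0.920 to 0.972. The wild type pair was not the closest among these 5. Its libraries correlated at 0.935, and wild type library 2 correlated with knockout libraries 5, 4 and 1 at 0.972, 0.970 and 0.960. Wild type library 1 stood apart on the second principal component, with 19.2% of the variance (77.1 against -38.8 to 11.3). The first component, with 55.4% of the variance, separated knockout libraries 2 and 3 from the rest. The Lys poly-A control, a bacterial transcript added to RNA samples before labelling, had signals of 12075 and 9157 in them and of 3168 to 4150 in the others. The Dap poly-A control had 17428 and 17124 in them and 8049 to 13798 in the others. Their log2 ratios of 3' to 5' probe sets were the 2 lowest of the 7 libraries for each transcript measured: 0.79 and 0.89 for Actb (1.46 to 2.08 in the others), 0.70 and 1.02 for Lys (1.5 to 2.3 in the others), 0.18 and 0.44 for Dap (0.88 to 2.32 in the others), and -0.31 and -0.27 for Gapdh (-0.17 to 1.32). Between wild type and knockout libraries, 8 control measures gave exact permutation p from 0.238 to 0.952, two-sided. With 21 splits a lone measure could not pass after adjustment over 8, so this does not show that they were equal. The largest differences were -0.91 for the Dap and -0.66 for the Lys 3' to 5' ratio (exact p = 0.238 for each). The log2 ratio of the 3' to the 5' Gapdh probe set was 0.37 ± 0.57 in wild type (n = 2) and 0.13 ± 0.68 in knockout libraries (n = 5, exact p = 0.857), and that of Actb was 1.77 ± 0.44 and 1.37 ± 0.50 (exact p = 0.429).

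**Figure D2:**
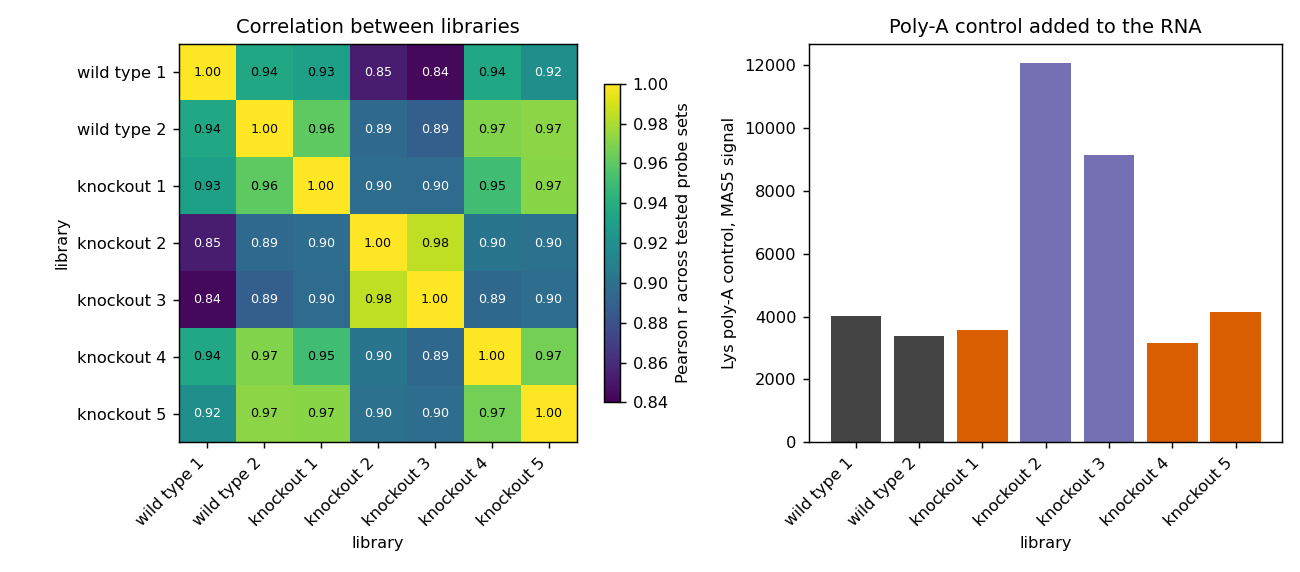
Pearson correlation between the 7 libraries across the tested probe sets (left) and the Lys poly-A control as MAS5 signal in each library (right, bars starting at 0). Knockout libraries 2 and 3 correlate at 0.985 with each other and at 0.902 or less with the rest, and their Lys signals of 12075 and 9157 lie above the 3168 to 4150 of the others.

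Genes that serve protein folding in the ER were higher in knockout libraries 2 and 3. In the other 3 knockout libraries their list median was near the wild type mean, but single genes could lie above it. Hsp90b1, an ER chaperone gene chosen after its values were seen, had signals of 9079, 9264 and 10735 in knockout libraries 1, 4 and 5. Both wild type libraries lay below, at 5247 and 7526. Without knockout libraries 2 and 3 it did not pass (0.62, limma adjusted p = 0.770). Over all 7 libraries, in the list of ER chaperones and glycoprotein folding, 35 of 37 measured members had a positive difference, with a median of 0.57 (camera adjusted p = 3.7e-05; adjusted p = 0.623 with an estimated correlation). The list's 2 brightest members were Canx, encoding the membrane-bound lectin chaperone related to calreticulin (11943 ± 530 in wild type, 13667 ± 1808 in knockout, difference 0.18), and Hspa5, encoding the ER chaperone BiP (10655 ± 2610 and 14064 ± 4126, 0.37). The unfolded protein and amino acid stress response list rose as well, by a median of 0.41 (21 of 28 positive, adjusted p = 0.0300; 0.623 with an estimated correlation), with Xbp1 at 0.08 and Asns at 0.23. So did calcium handling (0.37, 27 of 32 positive, adjusted p = 0.0132; 0.623 with an estimated correlation), where Atp2a2, the ER calcium pump, was at 0.08 and Calu at 0.75. The extracellular matrix list rose by 0.50 (25 of 32 positive, adjusted p = 0.0378; 0.723 with an estimated correlation), with Fn1 at 0.14 and Col18a1 at 0.55. None of the measured members of the 33 lists passed the threshold over all genes. The ER chaperone list kept its call whichever single library was left out. Calcium handling lost it without wild type library 2 (adjusted p = 0.109), the stress response without wild type library 2 (0.804) or knockout library 2 (0.134) or 3 (0.0825), and the matrix list without wild type library 1 (0.265) or 2 (0.0976) or knockout library 2 (0.277) or 3 (0.282). Over 22 alternatives the call was kept in 18 for ER chaperones, 16 for calcium handling, 13 for the stress response and 12 for the matrix list.

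These 4 rises lay mainly in knockout libraries 2 and 3. The ER chaperone list's median above the wild type mean was 1.22 and 1.33 in them and 0.12, 0.04 and -0.07 in knockout libraries 1, 4 and 5. The matrix list's was 1.19 and 1.29, against -0.20, -0.26 and -0.13. The stress response list's was 0.76 and 0.77, against -0.08, 0.30 and -0.18, where knockout library 4 lay above both wild type libraries (0.18 and -0.18). For calcium handling it was 0.78 and 0.86, against 0.11, 0.02 and 0.13 (0.02 and -0.02 in wild type libraries). Without the 2 libraries the ER chaperone list stood at 0.06 (adjusted p = 0.400), the stress response at 0.03 (0.752) and calcium handling at 0.12 (0.400). The matrix list turned to -0.16 there (0.0163, lower, and 0.520 with an estimated correlation). Fibroblast markers, included because feeder cells can accompany stem cell cultures, moved with the same 2 libraries. The list median was 0.64 and 0.76 in them and -0.65, -0.26 and -0.53 in the other 3 knockout libraries. Over all libraries it did not pass (0.02, adjusted p = 0.651), and without the 2 it was lower in the other 3 knockout libraries (-0.47, adjusted p = 0.000698; 0.520 with an estimated correlation). Its bright members Fn1 and Ccn2 stood at 0.14 and -0.29. Col1a1, chosen after its values were seen, had signals of 355 and 305 in the 2 libraries, 71.1, 215 and 83.4 in knockout libraries 1, 4 and 5, and 210 and 137 in wild type libraries.

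Of the lists of early development, those of the primed epiblast, mesoderm, primitive streak and Wnt targets were called as lower in the knockout group. Only the mesoderm list lay below both wild type libraries in all 5 knockout libraries. The lists of neural ectoderm, endoderm and trophoblast were not called. Markers of the primed epiblast, the state that embryonic stem cells enter on leaving naive pluripotency, fell (median -0.61, 13 of 17 negative, camera adjusted p = 0.0132; 0.623 with an estimated correlation). Its brightest members were the de novo DNA methyltransferase gene Dnmt3b (11007 ± 3137 and 7316 ± 2047, difference -0.61) and Lefty1 (0.48). Mesoderm and vascular progenitor genes fell (median -0.34, 14 of 19 negative, adjusted p = 0.0149; 0.623 with an estimated correlation). Adjusted over the list alone, 2 of them were lower, Vim and Lmo2 (-1.78), a haematopoietic transcription cofactor gene, while Pecam1, the list's other bright member, was at 1.74. Primitive streak and mesendoderm genes fell (median -0.38, 7 of 9 negative, adjusted p = 0.0457; 0.623 with an estimated correlation), with Eomes at -0.38 and Foxa2 at -0.44, and 2 were lower adjusted over the list alone, the caudal homeobox gene Cdx2 (-1.92) and the endoderm gene Sox17 (-1.20). Wnt pathway targets fell (median -0.14, 14 of 21 negative, adjusted p = 0.0361; 0.623 with an estimated correlation), where Cdx2 and Myc (-1.49) were lower adjusted over the list alone and Fzd7 stood at 0.88 and Tcf7l1 at -0.09. Vim, Lmo2, Cdx2, Sox17 and Myc were chosen after their values were seen, and over all genes 0 members of these 4 lists were called. Without knockout libraries 2 and 3 the primed epiblast (-0.36, adjusted p = 0.00119), mesoderm (-0.39, 0.00395) and Wnt target (-0.25, 0.00572) lists still passed, and the primitive streak list did not (-0.47, 0.0566). In that fit the fibroblast markers (-0.47, 0.000698) and the primitive and visceral endoderm genes (-0.36, 0.00131) fell as far, so the lower medians are not confined to these lists. With an estimated correlation none of these lists passed there (adjusted p = 0.520 or 0.554). Calls were lost without wild type library 1 for the primed epiblast (median -0.24, adjusted p = 0.382), mesoderm (0.0634), Wnt target (0.0604) and streak (0.0694) lists. The primed epiblast list stood at 0.32 and -0.32 in wild type libraries 1 and 2, and knockout library 4 (-0.22) lay above the latter. The streak list stood at 0.09 in knockout library 5, above both wild type libraries (0.07 and -0.07). The Wnt target list stood at -0.0483 and -0.0689 in knockout libraries 1 and 2, within the wild type values of -0.0693 and 0.0693. The Wnt target list also lost its call without wild type library 2 (0.111) or knockout library 4 (0.0646), and the streak list without wild type library 2 (0.174) or knockout library 1 (0.0885), 2 (0.0561) or 4 (0.0511). With the filter at the 60th percentile the mesoderm list (-0.16, adjusted p = 0.154) and the Wnt target list (0.0843) lost theirs, as did the streak list with array weights (0.108). Over 22 alternatives the call was kept in 19 for the primed epiblast, 18 for mesoderm and 15 for Wnt targets, and over 21 in 9 for the primitive streak.

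Lists of growth and metabolism were called as lower too, but of the 5 below only the respiratory chain was lower in every knockout library. In knockout library 1 the ribosomal protein median over the wild type mean was 0.24 (0.03 and -0.03 in wild type libraries). Cell cycle stood at -0.0008 there (0.08 and -0.08) and glycolysis at -0.10 (0.17 and -0.17). The nuclear pore list stood at 0.02 and 0.04 in knockout libraries 1 and 4 (-0.01 and 0.01). Ribosomal proteins fell (median -0.20, 24 of 26 negative, camera adjusted p = 0.0132), cell cycle genes (-0.28, 28 of 37, 0.0132), the mitochondrial respiratory chain (-0.14, 32 of 38, 0.0137), glycolysis (-0.20, 17 of 23, 0.0149) and the nuclear pore and nuclear transport list (-0.22, 29 of 39, 0.0492). With an estimated correlation the adjusted p was 0.623 for the first 4 and 0.652 for the nuclear pore list. Among the brightest members, Rpl38 stood at -0.24 and Rpl27 at -0.30, the replication genes Mcm7 and Pcna at -0.28 and -0.38, Cox7a2 and Cox5a at -0.04 and -0.09, the glycolytic enzyme gene Pgk1 at -0.33, the glucose transporter gene Slc2a3 at -0.04, and Ran and Kpna2 at -0.26 and -0.37. Without knockout libraries 2 and 3 the respiratory chain (-0.12, adjusted p = 0.0163) and glycolysis (-0.26, 0.00898) still passed, but neither did with an estimated correlation (0.554 for each). Ribosomal proteins (-0.12, 0.0856), cell cycle (-0.19, 0.0601) and nuclear pore (-0.01, 0.651) did not pass there. Quantile normalization ended the call of all 5 lists (adjusted p = 0.919 for ribosomal proteins, 0.191 for cell cycle, 0.723 for the respiratory chain, 0.121 for glycolysis and 0.739 for nuclear pore), and turned the camera direction of the ribosomal and respiratory chain lists. The neighbours of Calr on chromosome 8 fell (median -0.28, 18 of 23 negative, adjusted p = 0.0492; 0.623 with an estimated correlation; 0.0566 without the 2 libraries; 0.0977 with quantile normalization), with Prdx2 at -0.50 and Syce2 at -0.37. Without wild type library 1 it stood at 0.02 (adjusted p = 0.652), and it lost its call without knockout library 3 (0.0522), 4 (0.115) or 5 (0.0765). Glycolysis lost its call without wild type library 1 (0.382). Without wild type library 2 the cell cycle (0.0738), respiratory chain (0.126), ribosomal protein (0.0976) and nuclear pore (0.646) lists lost theirs, and the nuclear pore list also without knockout library 2 (0.134) or 3 (0.147). Over 22 alternatives the call was kept in 18 for glycolysis, 17 for the respiratory chain, 15 for cell cycle, 14 for ribosomal proteins, 7 for the neighbours of Calr and 4 for the nuclear pore list.

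The markers of undifferentiated cells and of cardiac differentiation gave no call. Naive pluripotency genes had a median of 0.07 (31 measured, camera adjusted p = 0.768), with Dppa5a at 25226 ± 2259 in wild type and 24421 ± 5777 in knockout libraries and Zfp42 (Rex1) at 12691 ± 4222 and 12634 ± 3052. The list passed as lower without wild type library 1 (-0.19, adjusted p = 0.0228) and as higher without wild type library 2 (0.30, adjusted p = 0.0430), so its direction depends on which wild type library is used. Cardiac transcription factors and progenitor genes stood at -0.25 (19 measured, adjusted p = 0.194), with Id2 at -0.52 and Foxh1 at -0.06. The sarcomere list stood at -0.27 (0.106), with Actn1 at -0.31 and Tpm4 at -0.36, and passed without knockout library 4 (-0.38, adjusted p = 0.0360). The calcineurin, NFAT and MEF2 list, which holds calcium-dependent signalling genes, had a median of -0.03, a mean of 0.04 and a camera direction upwards (0.980), and its brightest members Fkbp1a and Ppp3cb at -0.37 and 0.26.

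The other lists not called over all libraries covered adhesion, metabolism, stress and immunity. Integrins, cadherins and cell junctions stood at 0.40 (camera adjusted p = 0.0708; medians of 0.76 and 0.85 in knockout libraries 2 and 3), with Cdh1 (E-cadherin) at 0.31 and Ctnnb1 at -0.24. They passed without wild type library 1 (0.0139) or knockout library 4 (0.0268) or 5 (0.0360). Focal adhesion and actin genes stood at -0.26 (0.0845; 0.0163 without wild type library 2, 0.0324 without knockout library 4), with Actg1 at -0.48 and Actb at -0.01. The tricarboxylic acid cycle and fatty acid oxidation stood at -0.20 (0.0845; 0.0491 without knockout library 4), with Mdh2 at -0.53 and Hadh at -0.33. Hypoxia response stood at -0.05 (0.362; Slc2a1 -0.01, Pdk1 0.24), cholesterol synthesis at -0.11 (0.331; Hmgcs1 -0.41, Sqle -0.02), interferon response at -0.52 (0.194; Ifitm3 -0.08, Trim25 -0.58), and p53 targets at -0.06 (0.980; Mcl1 -0.06, Ccng1 0.48). MHC class I antigen presentation stood at -0.42 (0.0757), with Canx at 0.18 and Pdia3 at 0.92, and passed without wild type library 2 (0.00811) or knockout library 2 (0.0382) or 3 (0.0355). Its direction depends on the wild type library used: the 2 stood at 0.66 and -0.66, and the difference was 0.18 (adjusted p = 0.602) without wild type library 1 and -1.08 without wild type library 2. Cholesterol synthesis (-0.29, adjusted p = 0.00131) and MHC class I (-0.44, 0.0273) passed as lower without knockout libraries 2 and 3 together. With an estimated correlation neither passed there (adjusted p = 0.554 and 0.564).

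Lists of further cell types were not called over all libraries either. The calls below without knockout libraries 2 and 3, of germ cell and endoderm genes, were lost with an estimated correlation (adjusted p = 0.554 for each). Trophoblast genes stood at 0.21 (camera adjusted p = 0.247), with the keratin genes Krt18 at 0.30 and Krt8 at 0.08. Adjusted over the list alone, Krt7 (1.03) was higher and Cdx2 lower, and both were chosen after their values were seen. Neural ectoderm stood at -0.16 (0.276; Stmn2 0.29, Foxd3 -0.59), and imprinted genes at -0.03 (0.362), with Slc38a4 at 0.86 and Mest at -1.29. Germ cell genes stood at 0.23 (0.276; Ifitm1 0.12, Ifitm3 -0.08) and passed without wild type library 2 (0.0430) and without knockout libraries 2 and 3 together (0.36, 0.0412). The 2-cell-like state stood at -0.55 (0.102; Eif1a -0.20, Usp17la -1.10) and passed without wild type library 1 (0.00650) or knockout library 5 (0.0206). Primitive and visceral endoderm had a median of 8.3e-05 and a mean of -0.00, with a camera direction downwards (0.362; Sparc -0.45, Apoe 1.08), and passed as lower without wild type library 1 (-0.22, 0.0356) and without knockout libraries 2 and 3 together (-0.36, 0.00131).

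In all, 14 of 33 lists passed with the preset correlation, 4 higher and 10 lower, against 0 with an estimated correlation and 0 with fry, a self-contained test (lowest adjusted p 0.194). With array weights 11 lists passed, 1 of them higher: the ER chaperone list kept its call at a smaller median (0.20, adjusted p = 0.0214), and the matrix list (0.06, 0.982), the stress response (0.11, 0.375) and calcium handling (0.26, 0.110) lost theirs. The count was also 11 without knockout libraries 2 and 3, with 1 list higher and 5 lists shared in the same direction: primed epiblast, mesoderm, Wnt targets, respiratory chain and glycolysis. With an estimated correlation and without these 2 libraries, 0 lists passed (lowest adjusted p 0.520). Without wild type library 2 it was 9.

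**Figure D3:**
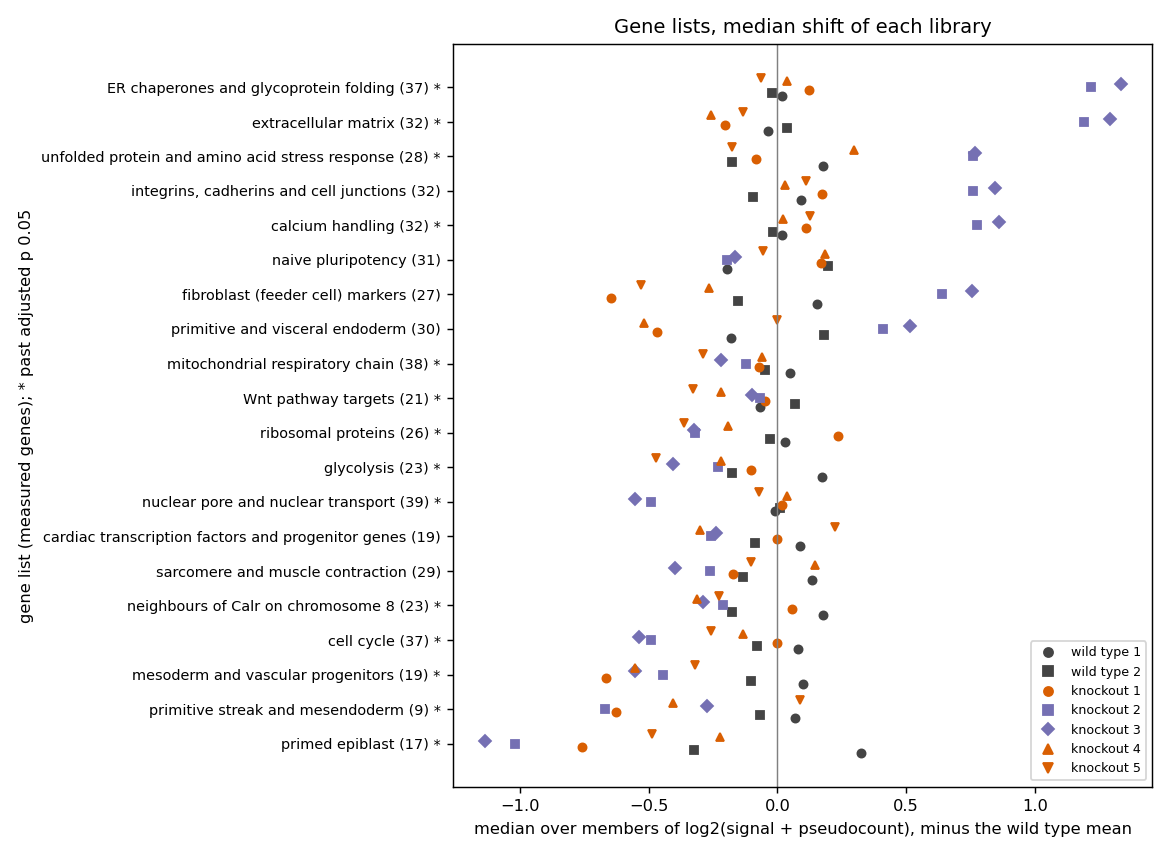
Median over the measured members of each list (their number in brackets) of log2(signal + 20.2) minus the wild type mean, 1 symbol per library; lists with a star passed adjusted p 0.05. The ER chaperone and matrix lists lie between 1.19 and 1.33 in knockout libraries 2 and 3 and between -0.26 and 0.12 in knockout libraries 1, 4 and 5, and mesoderm genes lie between -0.67 and -0.32 in all 5 knockout libraries.

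Of 20 chromosomes, the genes of chromosome 11 were called as lower and those of chromosome X as higher in the knockout libraries, the latter in 15 of 21 alternatives. Chromosome 11 (1093 genes) had a median difference of -0.23 (camera adjusted p = 1.98e-05; adjusted p = 0.516 with an estimated correlation). Relative to each library's own median, its genes stood at 0.17 and 0.12 in the wild type libraries, at -0.19 and -0.20 in knockout libraries 2 and 3, at -0.02 in knockout libraries 1 and 5, and at 0.13 in knockout library 4, which is within the wild type values. Chromosome X (435 genes) had a median of 0.15 (adjusted p = 0.0357; 0.483 with an estimated correlation). Relative to each library's own median its genes stood at -0.14 and -0.03 in the wild type libraries, -0.04 in knockout library 1 and 0.05 to 0.07 in the others. Of the Y chromosome genes with a tested probe set, Eif2s3y had signals of 3314 ± 2187 and 2715 ± 602, Uty of 790 ± 508 and 553 ± 73.4 and Uba1y of 1574 ± 455 and 1589 ± 228 in wild type and knockout libraries. The log2 differences were -0.14, -0.35 and 0.03, and each gene overlapped between the groups. Both chromosomes passed without knockout libraries 2 and 3 (-0.16, adjusted p = 0.000567, and 0.11, adjusted p = 0.00807), and neither did there with an estimated correlation (0.838 for each). Chromosome X lost its call without wild type library 1 (adjusted p = 0.945), knockout library 4 (0.177) or knockout library 5 (0.0833), without a filter on dim probe sets (0.07, 0.462) and with the replicate block (0.08, 0.554). Its median turned to -0.02 with centring on array medians, where all genes moved lower.

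**Figure D4:**
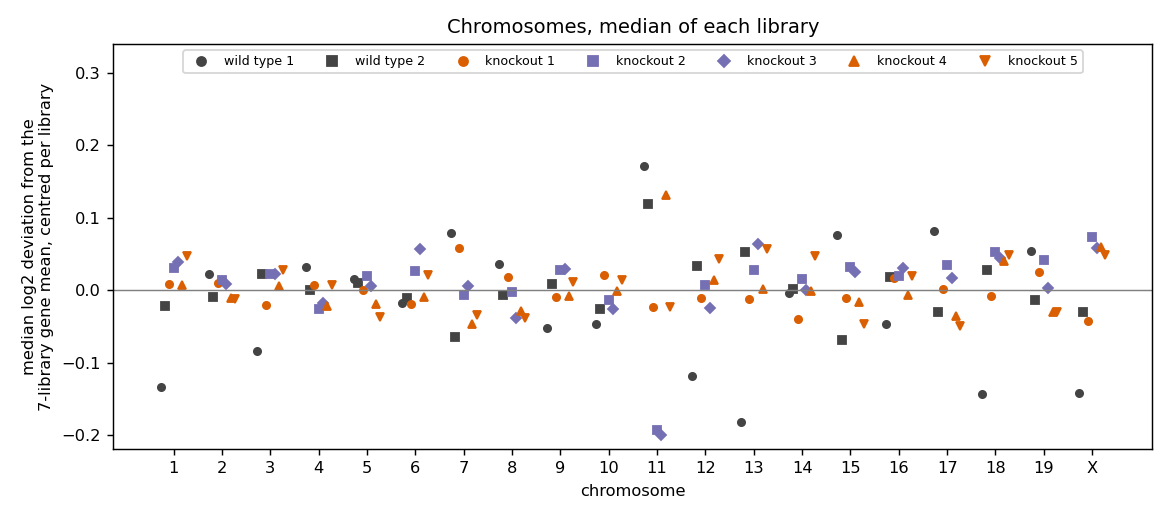
Median over the genes of each chromosome of the log2 deviation from the gene's mean over 7 libraries, minus the library's median over all genes, 1 symbol per library. On chromosome 11 both wild type libraries and knockout library 4 lie between 0.12 and 0.17, and knockout libraries 2 and 3 at -0.19 and -0.20.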

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

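Of the tests in this part, the Slc and Tmem test of the unfolded protein response was written before its result was seen; the Slc25 test was added after the Slc and Tmem results were seen, and all others were chosen after theirs. In groups of 5 libraries a lone value is marked when its gap to the nearest other exceeds 0.71 of the group's range, and chance marks about 1 in 20. Of 51 values tested over the knockout libraries, 5 were marked. The second brightest Calr probe set had a gap of 0.731 of the range, with knockout library 4 lowest at a signal of 489 against 813 to 978. The Gapdh 3' to 5' log2 ratio had a gap of 0.762, with knockout library 4 at 1.32 and the others at 0.08 or less. The ribosomal protein list had a gap of 0.713, with knockout library 1 at 0.24 and the others at -0.19 or less. The neighbours of Calr had a gap of 0.726, with knockout library 1 at 0.06 and the others at -0.21 or less. Chromosome X had a gap of 0.793, with knockout library 1 at -0.04 and the others at 0.05 or more.

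Knockout libraries 2 and 3 differed from the other 5 far more than the groups differed. The ER, calcium, matrix and stress response lists rose in them, which could reflect an unfolded protein response or a shared property of many transcripts, translation at the ER membrane. These were tested on gene families chosen by their symbols. In the 2 libraries against the other 5, solute carriers (Slc genes, 247) had a median shift of 0.60 and Tmem genes (167) of 0.56, each above all 10000 random sets matched on signal, which argues against an unfolded protein response as the whole cause, since neither family is a class of stress targets. The Slc25 carriers, mitochondrial proteins made on free ribosomes, stood at -0.00 (40 genes) against 0.74 for the other 207 Slc genes. The Psm, Eif and Polr families of soluble proteins stood at -0.66 (119 genes, matched random sets at a median of -0.29). Mitochondrial ribosome genes were also lower than their matched sets (-0.54 against -0.26). Ribosomal proteins (-0.26 against -0.36) and Zfp genes (0.02 against 0.03) did not fall below the 5th percentile of theirs. The respiratory chain (-0.13 against -0.37) lay at percentile 97.9 of its matched sets, on the high side. The fall was thus not shared by all of these sets, and a higher share of ER-translated transcripts remains only a candidate explanation. Separate handling of the 2 RNA samples stays open too: the lower of their Lys poly-A signals was 2.21 times the highest of the other 5, the 3' to 5' ratios of the added Lys and Dap transcripts, which do not come from the cells, were lowest in them, and uneven recovery of membrane-bound RNA could give the same profile; a difference between the cultures was not tested.

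The 21 ways to choose 2 of the 7 libraries included 2 with at least 8 changed probe sets, so chance cannot be excluded by this count alone: the real one and the choice of knockout libraries 2 and 3, which gave 7771 and follows the poly-A control signals, a structure of the samples. The same 2 choices gave at least 2 changed genes, with 4279 for knockout libraries 2 and 3. With these 2 libraries as a batch term the real comparison gave 10 probe sets and 7 genes. No other choice was fitted with a batch term, so these 2 counts have no reference among the choices. Among the other 5 libraries, the real choice gave 5 probe sets and 1 gene and the highest of the other 9 gave 1 and 1. Calr, the targeted gene, supplied 3 of the 8 and 3 of the 5 probe sets, 1 of the 2 genes and the 1 gene here. These counts thus say little about changes beyond Calr, and 10 choices are too few for a share under 0.05.

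The called Snhg14 probe set stood at 6.7 and 19.6 in wild type libraries and at 1706 or more in knockout libraries. A fault of this probe set alone is argued against by the other probe sets of the gene, of which 2 of 2 had all 5 knockout signals above both wild type signals. A change of the whole imprinted region as large as that of the called Snhg14 probe set is argued against by the neighbours Ndn, Magel2 and Ube3a. Their median difference was -0.0339, with Magel2 at -0.31 and Ube3a at 0.94 (limma adjusted p = 0.589), all far from the 6.30 of that probe set. The brightest Snhg14 probe set, at 1004 ± 437 in wild type libraries, differed by only 1.79. Against that value Ndn and Magel2 had negative differences, but Ube3a was not clearly apart from it. A smaller change cannot be excluded, since the Ndn signals alone were 2131.5 and 964.6 in wild type libraries 1 and 2. A change of transcription or processing within Snhg14 in the knockout cells may remain, and whether it comes from the loss of calreticulin or from the history of the knockout cells was not tested.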

How the results depend on the processing

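The alternatives without knockout libraries 2 and 3 (with either correlation) and with them as a batch term were added after the data were seen; all others were planned. Calr kept its direction in 20 of 20 alternatives and its call in 18. With a lone wild type library, assumed to vary like the knockout group, the targeted gene difference was -3.58 (without library 1) and -3.78 (without library 2); over all libraries left out in turn it ranged from -3.78 to -3.52. Left-out libraries gave 0 to 7 changed probe sets, 0 to 2 changed genes, 9 to 15 lists and 1 to 3 chromosomes. The main counts were 8, 2, 14 and 2.

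The numbers of changed probe sets, changed genes, lists and chromosomes moved by over 1.5 times as follows; the cause was not tested. Quantile normalization gave 9 lists. Without a filter on dim probe sets there were 5 probe sets, 1 gene and 1 chromosome. With the filter at the 60th percentile there were 4 probe sets, 1 gene and 9 lists. Camera with an estimated correlation gave 0 lists and 0 chromosomes, and fry gave 0 lists. Without knockout libraries 2 and 3 there were 5 probe sets, all among the 8, and 1 gene, and with an estimated correlation 0 lists and 0 chromosomes. With them as a batch term there were 7 genes. The replicate block gave 15 probe sets, 7 of them among the 8, 42 genes and 1 chromosome; same-numbered libraries deviated with r = 0.11 and -0.01, so the numbers are not known to pair them, and with 2 shared numbers the block rests on few libraries.

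Some lists changed direction. With quantile normalization, camera placed the respiratory chain (median -0.000289) and ribosomal proteins (-0.0180) above other genes. Without wild type library 1, naive pluripotency stood at -0.19 (adjusted p = 0.0228), and without wild type library 2 at 0.30 (0.0430; range over alternatives 0.0228 to 0.970). Without knockout libraries 2 and 3, and with the batch term, the matrix list stood at -0.16 and fibroblast markers at -0.47. The median of all genes moved to -0.09 with quantile normalization and to -0.17 with centring on array medians, from -0.00, a shift over 0.1 for the latter. Among single probe sets, Bcl11b kept its call in 4 of 18 alternatives and Mid1 in 10 of 17. Low signals, under the pseudocount of 20.2 in 18.3% to 21.8% of probe sets per array, limit the folds of Snhg14 and of the probe set annotated to 2 genes.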

Other observations

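All gene order tests in this part were chosen after the differences had been seen, and the genes named here were chosen after their values were seen. Genes were ordered along each chromosome (GRCm38.p6) and the median difference was taken over windows of 15 tested genes. The window farthest from 0 without knockout libraries 2 and 3 lay near the end of the X chromosome, from Vegfd to Prps2. In all 7 libraries its 15 genes all had a positive difference, with a median of 0.79, and without the 2 libraries the median was 1.15. Mospd2 stood at 1.95, Fancb at 1.46, Ofd1, a centriole gene, at 1.77 and Egfl6 at 2.25, and none of the 4 passed the threshold singly. The 15 genes before the window had a median of 0.02. Beyond it, Msl3, Amelx and Hccs stood at 0.22, 0.18 and 0.19, and then came Mid1 at -3.01. Without the 15 genes, chromosome X still had a median of 0.12.

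The run on the X chromosome was weighed against 2 explanations. A chance run of neighbouring genes that vary independently is argued against by shuffled gene orders. Without knockout libraries 2 and 3, 0 of 1000 shuffles (0%) held a window as far from 0 anywhere in the genome. With all 7 libraries 14 of 1000 did. The shuffles treat neighbouring genes as independent and did not exchange libraries. They therefore cannot exclude neighbours that vary together between cultures apart from genotype. An extra copy of the segment in the knockout line may give a shift near 1: the median over the wild type mean was 0.87, 1.04 and 0.94 in knockout libraries 1, 4 and 5, but 0.36 and 0.40 in knockout libraries 3 and 2, lower than an extra copy in every cell would give. No DNA was measured, so whether any or all knockout libraries carry such a segment stays open, as does an effect of losing calreticulin.

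A window of lower genes lay on chromosome 12, from Bcl11b to Mirg, with a median of -0.92 in all 7 libraries (1 of 1000 shuffles as far from 0) and of -0.66 without knockout libraries 2 and 3 (3 of 1000). Bcl11b at its edge was at 2.41, while Setd3 (-1.30), Ccnk (-1.22), Evl (-1.26), Yy1 (-0.92), Wars (-1.24) and the imprinted genes Rian (-0.92) and Mirg (-1.07) had signals below both wild type libraries in all 5 knockout libraries. Dlk1 (-1.13) overlapped between the groups, and the tested probe sets of Meg3 ranged from -2.67 to 0.30. With 1 probe set per gene none of these genes passed the threshold singly with all 7 libraries. Over probe sets Bcl11b did (adjusted p = 0.0491) and the others did not. With all 7 libraries a window on chromosome 11 from Tubg1 to Rnd2 stood at -0.85 (4 of 1000), and windows of higher genes on chromosomes 17 (0.77, 25 of 1000) and 13 (0.75, 46 of 1000) were also rarer than 5%.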
